A study of Onthophagus taurus with 48 samples.

How the data were processed

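RNA of the horned beetle *Onthophagus taurus* was compared on 48 two-colour NimbleGen arrays, which hold 60-base probes and read 2 labelled samples against each other on the same surface. Per the labels, total RNA was extracted with Trizol, primed with oligo-dT, turned into double-stranded cDNA and labelled with Cy3 or Cy5. The 16 RNA types combined 2 nutritional conditions, 2 sexes and 4 body regions (head, thorax, leg and abdomen), and per the series' design text each type was a pool of 4 animals. An RNA type is written below by 3 letters, as in the sample titles: L or S for optimal or suboptimal nutrition, M or F for male or female, and H, T, L or A for head, thorax, leg or abdomen. An array is written with its Cy3 RNA first.

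The authors deposited for each array 1 normalized log ratio per probe, taken here as log2. The base of the logarithm, the dye in the numerator, the background correction, the normalization, the scanner software and the slide that carried each array are not given in the sources used here. Base 10 was set aside because values reached 7.03 and -7.06. Base 2 was assumed over the natural logarithm, and no test or correlation depends on that choice. The deposited values had no missing entry. Array means lay between -0.0098 and 0.0066 and array medians between -0.073 and 0.057, so the arrays had been centred before deposit. The value table of the whole series differed from the array files by at most 5e-08. Because the numerator dye is unknown, values were coded as Cy5 over Cy3, and differences are reported as lying on a plus or a minus side under that coding. Every sign turns together if Cy3 was the numerator. Counts, sizes, correlations and agreement of sides between comparisons are the same under either reading.

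The 124898 probes belonged to 42010 contigs, the assembled or single sequences from which the array was designed. A contig had a median of 3 probes, 9462 contigs had 1 probe, and a contig's value was the mean of its probes. The files do not pair contigs with genes. None of the 42010 contig names was found in the gene table supplied for this beetle (0 matches), so no gene is named, and the gene lists fixed before the data were examined could not be tested. Contigs are identified by the names in the files and by the position of a probe within the contig. No genome position is given.

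A linear model with 15 differences between RNA types and a dye effect was fitted to all 48 arrays with limma 3.58.1 in R 4.3.3, leaving 32 residual degrees of freedom. The dye term was needed because all 8 male to female arrays carried male RNA in Cy3. Comparisons within a region were contrasts of this fit with moderated statistics. Their p-values rest on the spread between hybridisations, which may be technical, because the labels do not say which arrays carried separate pools. Comparisons across strata (each region against the other 3, male against female, optimal against suboptimal) were planned as a limma fit of the 16 fitted RNA values with strata as blocks. In simulated data, the plain form of that fit gave an unadjusted p under 0.05 for 30.6% of contigs with no simulated sex difference, because fitted values share array errors. The covariance of these errors, plus a variance for each RNA type estimated over all contigs, was therefore built into the fit. This change was made after the counts of the plain fit on the real arrays had been seen, and the plain fit is kept as an alternative. With the errors modelled the share was 5.01% for sex, 5.08% for nutrition and 4.7% for the abdomen. In the same simulation of 42010 contigs, 200 contigs changed by 1 log2 unit in each comparison were recovered at 71.5% for sex, 81.5% for nutrition and 87.5% for the abdomen. With a simulated RNA variance of 0.1, treating the 48 arrays as the unit gave a p under 0.05 for 20.2% of contigs for sex and 27.9% for nutrition, against 4.8% and 4.92% in the fit used here. That variance was larger than the 0.0262 for sex and 0.0172 for nutrition estimated from these arrays, and with none added the array unit gave 4.99% and 4.98%. The inflation at the estimated variances was not simulated. Benjamini-Hochberg adjustment ran over all contigs, with a threshold of 0.05. With no difference, about 5% of the 42010 contigs would have an unadjusted p under 0.05. Such counts near or below that share are therefore no sign of a difference.

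Contigs were picked for naming by a rule fixed before the data were examined: past the threshold, with the same sign in every stratum, and with the largest change (for the interactions, the smallest p), limited to at most 2 on a side because contigs carry no gene names. Region profiles were the fitted region values of the region arrays of a stratum, and each region was set against the mean of the other 3. An array was compared with the profile of the 16 optimal region arrays over all contigs, leaving out the array itself where it was among them. Each region array was also compared with the optimal profile of the other sex, a match added after the first one had been seen. Correlations are over contigs, which are not independent replicates, so no p is given for them. Between contrasts 29 such relations were computed, some of them chosen after overlaps of calls had been seen. The 6 between nutrition differences of different regions ranged from 0.193 to 0.522 and are not taken up further. Noise-only data were simulated on the same array layout to give the correlation that shared arrays produce by themselves.

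The alternatives planned before the data were examined and run were centring on array medians, no dye effect, the median of the probes, the series value table, dye-swap pairs averaged, each array left out, the other unit of replication, and direct arrays only. Background correction, another normalization, a filter on dim probes and slide as a block were planned but not run, since the values used are ratios without intensities or slide names. Alternatives chosen after seeing the data were the plain fit, array weights, removal of spatial trends in blocks of 40 array positions, optimal or suboptimal arrays alone, and the fit without 7 doubted arrays. A region array was doubted where another region pair correlated with it better than the pair on its label by more than 0.1, and a sex or nutrition array where any region pair correlated with it above 0.5. Both limits were set after the correlations had been seen, and the array labelled SMA-SFA lay just under the second at 0.482. An exploratory list had held 10 arrays. A first rule without the margin of 0.1 doubted 11 arrays, 2 of them region arrays of optimal animals, and is kept as an alternative for the counts. For arrays the number of hybridisations limits the precision, and the median standard error was 0.19 log2 for sex within the head and 0.14 for nutrition within the head.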

Results

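The series asked how gene expression in a horned beetle, whose males grow head horns with good larval nutrition, differs with nutrition, sex and body region. The 48 arrays formed a network over 16 RNA types: 28 arrays compared 2 regions within a sex and nutritional condition, 12 compared optimal with suboptimal nutrition within a sex and region, and 8 compared male with female within a region and nutritional condition. Region arrays numbered 10 for optimal males and 6 for each of the other 3 combinations. Nutrition arrays numbered 4 for head, 4 for thorax, 2 for leg and 2 for abdomen. The network had 40 RNA pairs, of which 8 were hybridised in both dye orientations. Probe values on an array had a standard deviation of 0.468 to 1.27, and the intraclass correlation between probes of a contig was 0.416 to 0.822, with a median of 0.683. Region accounted for 57.4% of the variance of the fitted RNA values beyond noise, sex for 31.7%, nutrition for 2.38%, region by sex for 3.9%, sex by nutrition for 2.08%, region by nutrition for 1.5% and the 3-way term for 1.03%. These shares were not stable: without 7 arrays doubted below, region took 69.4%, sex 22.7% and region by sex 1.75%. Those arrays were doubted by how they matched region profiles, so this shift is partly set by the selection. Nutrition took 0.251% with dye-swap pairs averaged and 4.26% without the array LML-SML, and the 3-way term 0.502% without SML-SFL and 1.8% without SFH-SFA. Region by nutrition took 0.299% with dye-swap pairs averaged and 0.955% (without SFH-SFT) to 2.36% (SMA-SML) with single arrays left out, and region by sex 2.13% without SML-SFL.

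Across the 4 combinations of sex and nutrition, the abdomen stood furthest from the other regions. Of 42010 contigs, 13276 (31.6%) differed between abdomen and the mean of the other 3 regions at an adjusted p under 0.05, 7804 on the plus side and 5472 on the minus side, with a median size of 0.67 log2. Once arrays were centred on their medians, 6686 of 12938 lay on the plus side. The leg had 2772 such contigs (1277 plus, 1495 minus), the thorax 2136 (1202 plus, 934 minus) and the head 1996 (1011 plus, 985 minus). Of these, 13172 abdomen, 2625 leg, 2133 thorax and 1996 head contigs kept their sign in all 4 combinations. The calls rest on the mean over the same 4 combinations, so this agreement is largely set by the selection. The profile of each region correlated between strata that had no region array in common. Each region is set against the mean of the other 3, so the abdomen also enters the head, thorax and leg profiles and counts. These need not be particular to the region named. Between optimal males and optimal females the profiles correlated at r = 0.58 for head, 0.593 for thorax, 0.684 for leg and 0.792 for abdomen. Between optimal and suboptimal females the values were 0.609, 0.428, 0.789 and 0.899, and between optimal and suboptimal males 0.646, 0.681, 0.374 and 0.733. The leg of suboptimal males was the exception, with r = 0.204 against optimal females and 0.231 against suboptimal females.

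The files do not pair contigs with genes, so the largest differences are given by contig. For the abdomen, contig13230 (6 probes, the first at contig positions 86 to 145) differed by 4.54 ± 0.57 log2 (SE, limma adjusted p = 2.09e-04), on the plus side in 4 of 4 strata. For the thorax and the head alike the contig with the largest plus-side difference was OtP011_seq_F05_013007d_019 (1 probe at positions 583 to 642), at 4.11 ± 0.26 for the thorax (limma adjusted p = 8.48e-05) and 3.74 ± 0.26 for the head (limma adjusted p = 6.91e-05), in 4 of 4 strata each. For the leg it was OtL002_seq_H10_082906a_033_ab1 (3 probes, the first at positions 90 to 149), at 3.77 ± 0.63 (limma adjusted p = 0.00978), with stratum values from 2.22 to 5.56.

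Some region arrays matched another region pair better than the pair on their label. All 16 region arrays of optimal animals correlated with the region pair they named within 0.1 of their best pair, at r = 0.48 to 0.856. Among the 12 region arrays of suboptimal animals 4 did not. The margin of 0.1 was chosen after these values were seen, and with no margin the numbers were 2 of 16 and 6 of 12. This reference came from optimal arrays, some of which share RNA with the optimal arrays matched. Matched to the optimal profile of the other sex, which shares RNA with no array matched, 0 of 16 optimal and 3 of 12 suboptimal arrays lay beyond the margin. The array labelled SMT-SML correlated at 0.22 with thorax against leg and at 0.782 with thorax against abdomen. The array labelled SMA-SMT correlated at 0.238 with its own pair and at 0.652 with leg against head. The arrays labelled SMH-SML and SFH-SFT had own correlations of 0.153 and 0.081, against 0.41 and 0.274 for another pair. The better pair was not always the same on the profile of the other sex. There SMT-SML matched head against abdomen best, at 0.711. SFH-SFT matched head against leg best, at 0.144 against 0.0955 for its own pair, within the margin. SMA-SMT and SMH-SML kept their best pairs. Among arrays within a region, those labelled SML-SFL, SMT-SFT and SFH-LFH followed a region pair at r = 0.773, 0.605 and 0.519. Without these 7 arrays the counts were 14452 for abdomen, 6500 for leg, 4100 for thorax and 2817 for head, and 12708, 2694, 1894 and 1731 of those contigs were also called with all arrays. The region arrays among the 7 were picked for a poor match to the optimal region profile. Their removal can therefore raise region counts by construction, and the higher counts are no separate evidence against these arrays. Single arrays moved the leg count to 1072 (without SMA-SML), 1730 (SFL-SFT), 1821 (LFH-LFL), 4177 (SML-SFL) and 4715 (SMT-SML), the thorax count to 1366 (LFH-LFT) and 3374 (SML-SFL), and the head count to 1316 (LMA-LMH). Optimal arrays alone gave 8448 contigs for abdomen, 1233 for leg, 392 for thorax and 246 for head. Suboptimal arrays alone gave 1953 for abdomen, 16 for thorax, 1 for head and 0 in limma for leg, where 4672 had an unadjusted p under 0.05.

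**Figure D1:**
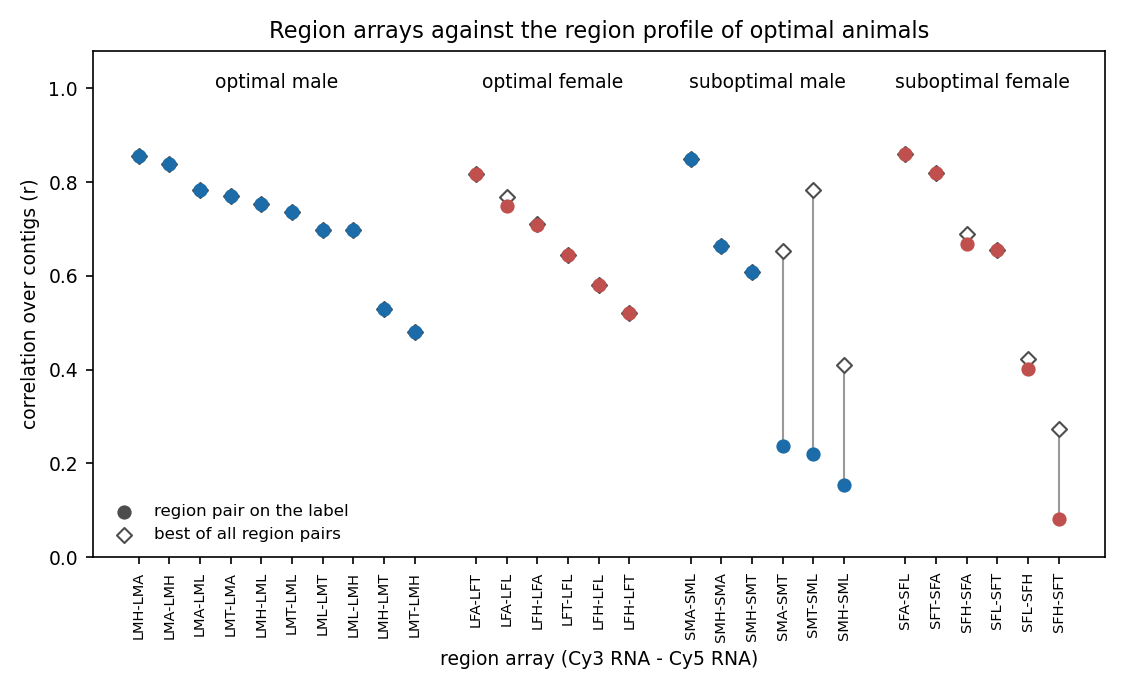
Correlation over contigs (r, vertical axis) of each of the 28 region arrays with the region profile of optimal animals, filled for the region pair on the label and open for the best pair; blue marks male and red marks female arrays. The 16 optimal arrays lie between 0.48 and 0.856, and 4 suboptimal arrays lie at 0.238 or below on their own pair with a better pair elsewhere.

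With all 48 arrays fitted together, male and female RNA differed in each of the 4 regions, and contigs shared between regions lay mostly on the same side. Across the 8 combinations of region and nutrition, 6531 contigs (15.5%) differed by sex, with a median size of 0.80 log2, and 6317 of them had the same sign in all 8. The calls rest on the mean over the same 8, so that agreement is largely set by the selection. The plus side of male over female held 3309 of the 6531 contigs, but 2555 of 6145 with arrays centred on their medians, so the side with more contigs turned. Within regions, 11055 contigs differed in the leg, 7349 in the thorax, 3004 in the head and 606 in the abdomen. With the 16 fitted RNA values as the unit, limma gave 5176, 2266, 0 and 0 in that order, and 7825 head and 4619 abdomen contigs had an unadjusted p under 0.05. In simulated data with 200 changed contigs this unit recovered 0% of sex changes of 1 log2 unit in each region. It did call leg and thorax contigs here, so that 0% does not give its power on these arrays. A count of 0 is still no evidence that a difference was absent. Direct arrays alone gave 0 in limma in all 4 regions, with 6853, 7852, 1156 and 3779 contigs at an unadjusted p under 0.05 and 4 residual degrees of freedom. The direct fit had no dye term, which these arrays cannot separate from sex, so any dye effect enters its counts. The head count of 1156 lies below the 5% of contigs that no difference would give. Contigs called in more than 1 region lay almost always on the same side: 2548 of 2548 shared by head and thorax, against 526 that independent lists of these sizes would share, 5046 of 5048 shared by thorax and leg against 1930, and 528 of 528 shared by leg and abdomen against 159. The fitted differences share arrays, and noise alone gave r = 0.451 between the sex differences of head and thorax where 0.88 was found, with a covariance of 0.264 against 0.0323. On the direct arrays, which share none, the optimal and suboptimal sex differences correlated at 0.676 in thorax, 0.433 in leg, 0.182 in abdomen and -0.052 in head. The suboptimal arrays behind the thorax and leg values, SMT-SFT and SML-SFL, are doubted for following a region pair. The lower abdomen and head values involve no doubted array. Between regions these arrays varied: head and thorax correlated at 0.357 on the optimal and -0.0493 on the suboptimal arrays, and head and leg at 0.185 and -0.0678. Head and abdomen gave 0.0811 and 0.0183, thorax and leg 0.544 and 0.502, thorax and abdomen 0.248 and 0.755, and leg and abdomen 0.468 and 0.73. Every suboptimal value with thorax or leg involves a doubted array, and none of the optimal values does.

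The contig with the largest minus-side sex difference was contig37480 (1 probe at positions 135 to 194), at -3.74 ± 0.35 log2 (SE, limma adjusted p = 0.00273, same sign in 8 of 8 strata), and it was also the largest on that side within head, thorax and abdomen. Next came contig31511 (2 probes, the first at positions 19 to 78), at -3.37 ± 0.62 (limma adjusted p = 0.0109), from -5.06 to -0.88 over strata. On the plus side stood FQTIJGT02HOMZ4 (3 probes, the first at positions 1 to 60), at 3.50 ± 0.47 (limma adjusted p = 0.0044), and contig19805 (2 probes, the first at positions 136 to 195), at 2.63 ± 0.40 (limma adjusted p = 0.0063), each with the same sign in 8 of 8 strata.

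In the joint fit the sex difference ran against the thorax profile, but single sex arrays differed in this. Their slopes on the thorax profile were -1.53 for SMT-SFT, -1.44 for SML-SFL, -1.01 for SMA-SFA, -0.614 for LML-LFL and -0.5 for LMT-LFT, against -0.0736 for LMA-LFA, -0.0197 for SMH-SFH and 0.159 for LMH-LFH. The first 2 are doubted arrays. Of 515 contigs called both for thorax and for sex, 32 lay on the same side, and of 3025 called both for abdomen and for sex, 2774 did. For leg 99 of 465 did, and for head 184 of 390. The correlation over all contigs was -0.436 with the thorax profile and 0.401 with the abdomen profile, where noise alone gave -0.067 and 0.036. With the leg and head profiles it was -0.185 and -0.0567, where noise alone gave -0.124 and 0.153. Each profile is set against the other regions, so these values are not independent. Without the 7 doubted arrays thorax and abdomen gave -0.247 and 0.177, and leg and head -0.218 and 0.224. The 7 include 2 sex arrays doubted for following a region pair, so their removal lowers the thorax and abdomen values by construction. Sex counts rested heavily on the doubted arrays: without them 1740 contigs differed across strata, and 53 in the leg, 3442 in the thorax, 2099 in the head and 468 in the abdomen. Leaving out 2 of the 8 sex arrays also lowers the precision, so these falls are not all evidence of smaller differences. Without the 11 arrays of the first rule the counts were 1594 across strata, 50 in the leg, 4558 in the thorax, 539 in the head and 2411 in the abdomen. Optimal arrays alone gave 0 contigs in limma across strata, with 6440 at an unadjusted p under 0.05, suboptimal arrays alone gave 7717, and direct arrays alone, fitted without a dye term, gave 2347. Single arrays took the count across strata to 3234 (without SMA-SFA), 3706 (SMT-SFT) and 3852 (SML-SFL), the leg to 2971 (SML-SFL) and the thorax to 3146 (SMT-SFT). The head went to 1499 (SFH-SFA), 1590 (SFH-SFT), 1675 (LFH-LFA), 1767 (SMA-SFA), 1948 (LFH-LFL) and 6079 (SMH-SFH). The abdomen fell to 7 (LMA-LFA), 11 (SMA-SFA), 158 (LFA-LFT), 171 (LFA-LFL), 214 (LML-LFL), 233 (SFA-SFL), 290 (SML-SFL), 353 (LFL-SFL) and 372 (SFL-SFH), and rose to 1043 (SFH-LFH), 1067 (SFH-SFA), 1281 (SMH-SFH), 1397 (LMH-LFH) and 1481 (LFH-LFA). All sex arrays carried male RNA in Cy3, so a dye effect of these arrays alone cannot be separated from sex.

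**Figure D2:**
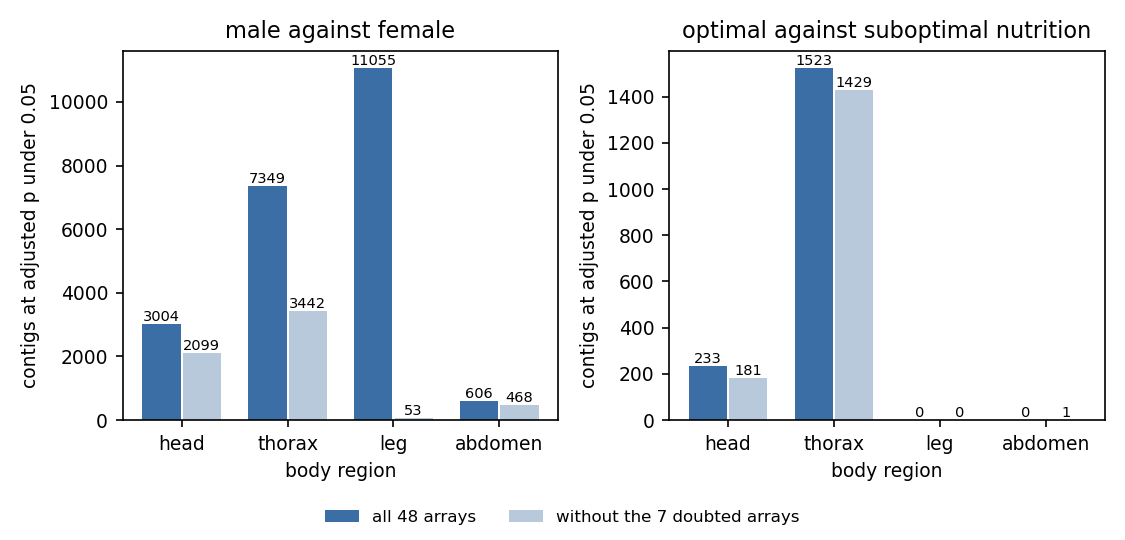
Contigs at an adjusted p under 0.05 (vertical axes, different scales) in each body region, left for male against female and right for optimal against suboptimal nutrition, with all 48 arrays (dark) and without the 7 doubted arrays (light). The leg drops from 11055 to 53 for sex, whereas the thorax has 1523 and 1429 for nutrition.

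Averaged over the sexes, contigs that differed with nutrition past the threshold lay in the thorax and the head. Their number is not evidence that regions responded differently, since the response was shown to differ between regions for 19 contigs. Simulated changes of 1 log2 unit were recovered at 77.5% in thorax, 81% in head, 71.5% in leg and 71% in abdomen. In this average 1523 contigs differed between optimal and suboptimal thorax, 792 on the plus side and 731 on the minus side, with a median size of 0.80 log2, and 1513 of them had the same sign in both sexes. The calls rest on the mean of the sexes, so this agreement is largely set by the selection. In the head 233 contigs differed (90 plus, 143 minus). In leg and abdomen no contig passed in limma, with 1621 and 2231 contigs at an unadjusted p under 0.05. The leg count lies below the 5% of contigs that no difference would give, and the abdomen count near it. Males alone had 161 leg contigs, but 7 without the 7 doubted arrays, 7 with dye-swap pairs averaged, and 9 (without SMT-SML) to 1006 (SMA-SML) with single arrays left out. Across all 8 combinations of region and sex no contig passed either, with 3763 at an unadjusted p under 0.05 and 35 with arrays as the unit. Without the 7 doubted arrays the counts were 1429 in thorax, 181 in head, 0 in leg and 1 in abdomen, and 1015 thorax contigs were called both ways. Averaging the dye-swap pairs left 6 contigs in thorax and 2 in head, and the 16 RNA values as the unit left 1 and 0. In simulated data the 16 RNA values recovered 45% and 47% of changes of 1 log2 unit. Direct arrays alone gave 396 and 0, and array weights 6756 and 489. Without the 11 arrays of the first rule the counts were 2463 in thorax, 339 in head and 14 in abdomen. Single arrays took the thorax to 217 (without SFT-LFT), 460 (SMT-LMT), 464 (LMT-SMT), 858 (SFH-SFT), 943 (LFT-SFT), 969 (LFH-LFT) and 2707 (LML-SML), and the head to 43 (LMH-SMH), 56 (SMH-LMH), 83 (SFH-LFH), 139 (SMH-SMT), 371 (SMA-SMT) and 401 (LML-SML). The abdomen reached 1 without SFT-SFA, LFH-LFA, LFA-LFT or SMA-SMT, 3 without SMA-LMA and 4 without SFA-SFL, and the count across strata 1 without LFH-LFT, SFA-LFA or SMH-SMA.

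In the thorax, contig32625 (4 probes, the first at positions 2 to 61) differed by -3.51 ± 0.81 log2 (SE, limma adjusted p = 0.0138), with -4.18 in males and -2.84 in females, and contig25790 (3 probes, the first at positions 32 to 91) by 2.24 ± 0.55 (limma adjusted p = 0.0183), with 2.39 in males and 2.08 in females. In the head, contig27571 (4 probes, the first at positions 172 to 231) differed by 1.54 ± 0.34 (limma adjusted p = 0.0223), and contig03424 (4 probes, the first at positions 74 to 133) by -2.78 ± 0.66 (limma adjusted p = 0.0397), of which -5.29 came from males and -0.26 from females. All 4 contigs missed the threshold once dye-swap pairs were averaged, at adjusted p = 0.339, 0.243, 0.486 and 0.521 in that order, with differences of -3.04, 2.24, 1.51 and -2.77. Single arrays also ended these calls: contig32625 went to adjusted p = 0.0628 (without LFT-SFT), 0.0502 (LMT-SMT) and 0.111 (SFT-LFT), contig25790 to 0.0781 (SFT-LFT), and contig27571 to 0.0805 (LFH-SFH), 0.0924 (LMH-SMH), 0.0671 (SFH-LFH) and 0.0599 (SMH-LMH). For contig03424 it was 14 of the 48 arrays: 0.219 (SFH-LFH), 0.103 (LMH-SMH), 0.0699 (SMH-SMT), 0.0697 (SMH-LMH), 0.0634 (LFH-SFH), 0.0596 (SMH-SML), 0.0588 (LFH-LFL), 0.0584 (SMA-LMA), 0.0572 (LFL-SFL), 0.057 (SFH-SFA), 0.0552 (LMH-LML), 0.0545 (LMT-SMT), 0.0524 (SFT-LFT) and 0.052 (LMT-LMH).

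The nutrition difference of the thorax lay along the thorax profile of the other sex. Regressed on the profile of optimal animals, the 4 thorax arrays had slopes of 0.357 and 0.421 in males and 0.433 and 0.377 in females. These were positive in both sexes and both dye orientations. The optimal profile holds any thorax response to nutrition that the sexes share, which by itself raises slopes on it. On the profile of suboptimal animals of the other sex the slopes were lower. They were 0.13 and 0.235 in males (r = 0.0875 and 0.176) and 0.342 and 0.336 in females (r = 0.281 and 0.235). Of 133 contigs called both for the thorax profile and for thorax nutrition, 131 lay on the same side, where independent lists would share 77.4. These 2 differences come from a joint fit and share arrays, and their correlation was 0.457 where noise alone gave -0.0741. The nutrition difference of the thorax also ran opposite to its sex difference: r = -0.613 over contigs, where noise alone gave -0.0023, and 11 of the 708 contigs called for both lay on the same side, against 266 shared by independent lists. On direct arrays alone the correlation was -0.448, and it was -0.305 with the optimal sex array only. Without the 7 doubted arrays it was -0.544.

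**Figure D3:**
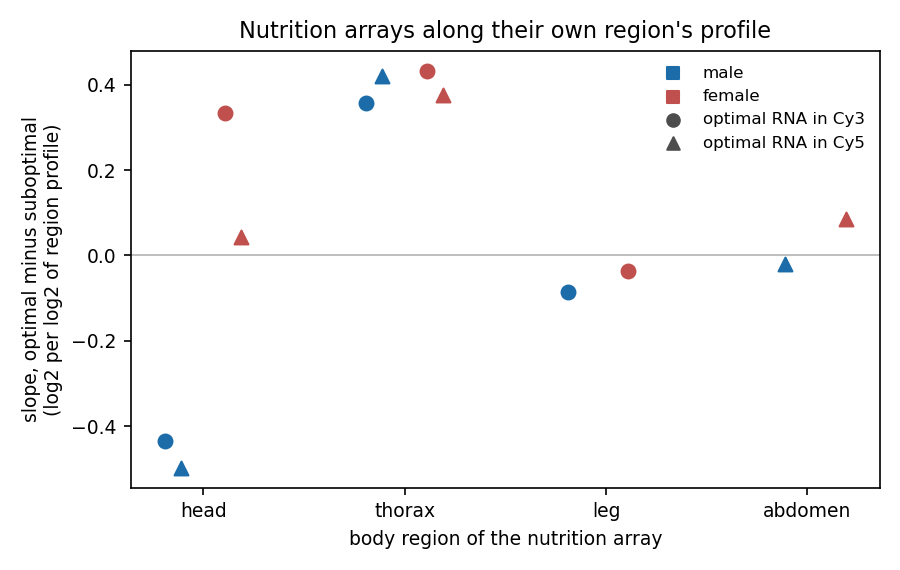
Slope of optimal minus suboptimal (vertical axis, log2 per log2 unit of the region profile) for each of the 12 nutrition arrays. The profile is that of the array's own region in optimal animals of the other sex. Colour gives the sex and symbol the dye of the optimal RNA. The 4 thorax arrays lie at 0.357 to 0.433, the male head arrays at -0.435 and -0.498, and the leg and abdomen arrays near 0.

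The response to nutrition differed between the sexes for 667 contigs in the F test over the 4 regions. Tested region by region, it differed for 399 contigs in the head, 576 in the leg, 38 in the thorax and 7 in the abdomen. Averaging dye-swap pairs left 51, 88, 8 and 3 in that order, whereas array weights gave 497, 832, 836 and 124. Leaving out single arrays gave 166 (without LMH-SMH) to 607 (LML-SML) in the head, 44 (SML-SFL) to 1218 (SMA-SML) in the leg, 6 (LMT-SMT) to 120 (SMA-SMT) in the thorax and 1 (LMH-LFH) to 49 (SFT-SFA) in the abdomen. In the male head 1981 contigs differed with nutrition, 1047 on the plus side and 934 on the minus side, but 342 with dye-swap pairs averaged, 664 without LMH-SMH, 4786 with array weights and 2765 without the 7 doubted arrays. In the female head no contig passed in limma. There 2201 had an unadjusted p under 0.05, near the 5% of contigs that no difference would give. The male head arrays in opposite dye orientation correlated at -0.581, a sign that turned with the dyes, whereas the female head arrays correlated at 0.115, so the swap did not turn the sign there. The female head arrays thus disagreed, and SFH-LFH among them is a doubted array. The absence of calls in the female head is therefore no evidence that females lacked a response. The slope on the head profile of the other sex was -0.435 and -0.498 in males and 0.334 and 0.0426 in females. The difference between the sexes in these slopes was not tested. In the thorax 713 contigs passed in males and 379 in females, 49 of them shared and all 49 on the same side. Averaging dye-swap pairs left 13 and 1. Leaving out single arrays gave 76 (without SMT-LMT) to 1359 (LML-SML) in males and 6 (SFT-LFT) to 822 (SMT-SFT) in females. Array weights gave 5232 and 2494, and the fit without the 7 doubted arrays 856 and 206. The male and female responses correlated at 0.553 in thorax, 0.128 in head, -0.218 in leg and 0.0019 in abdomen, where noise alone gave 0.146, 0.16, 0.18 and 0.207. Without the 7 doubted arrays the thorax value fell to 0.35. Leaving out single arrays took the head to 0.0247 (without SMH-SFH) or 0.229 (LFH-SFH) and the leg to -0.016 (LML-SML), and array weights took the leg to -0.069. The same correlations on direct arrays were 0.366, -0.064, -0.214 and -0.056.

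The smallest p for nutrition by sex belonged to contig17745 (5 probes, limma adjusted p = 1.32e-05). Its optimal minus suboptimal difference was 1.20 in the male head, 0.64 in the male thorax, 0.76 in the male leg and 0.49 in the male abdomen, against 0.017, -0.15, -0.00074 and -0.26 in females (SE 0.11 in each sex). Without the 7 doubted arrays 467 contigs differed between the sexes, 502 in the head, 134 in the thorax, 0 in the leg and 19 in the abdomen by region, and 260 of the 467 were also called with all arrays. Averaging dye-swap pairs left 63, array weights gave 1784, and the first rule for doubted arrays gave 1048. Single arrays took the 667 to 341 (without SML-SFL), 405 (LMH-SMH), 411 (LFH-SFH), 425 (SMT-LMT), 1036 (SMA-SML) and 1194 (SMA-SMT), and leaving out LML-LFL gave a count between 341 and 405. The response differed between regions for 19 contigs, for 72 without the 7 doubted arrays and for 251 without the 11 of the first rule. Single arrays took that count to 29 (without SMH-SML), 32 (SFT-SFA), 32 (SMT-SFT), 47 (SMA-SMT), 48 (SFL-SFH), 48 (SMH-SMA), 54 (SMT-SML) and 116 (SMA-SML). The smallest p for nutrition by region belonged to contig03777 (8 probes, limma adjusted p = 5.06e-04), with optimal minus suboptimal at -1.19 in the head, -0.28 in the thorax, 0.30 in the leg and 0.28 in the abdomen, averaged over the sexes. For contig03777 the head value held at -1.21 without the 7 doubted arrays, but the others fell to -0.152, 0.0582 and 0.104. Single arrays took its thorax to -0.433 (without LMT-SMT), -0.431 (SMT-LMT) and -0.176 (SFT-LFT), its leg to 0.477 (LML-SML) and its abdomen to 0.458 (SMA-LMA) and 0.18 (SMA-SMT).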

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

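The tests on shared RNA, dye orientation, common dye effects, noise between probes, loop closure and label matching were chosen after the results were seen, and the splits and the test of thorax tissue share before.

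The nutritional response differed between the sexes for 667 contigs in the F test, and by region for 399 in head, 576 in leg, 38 in thorax and 7 in abdomen. It differed between regions for 19 contigs. Among 27 groups checked for a sample far from the others, of which chance would pick out about 1 in 20, 2 stood out. The probe values of the array labelled SFH-SFA had a standard deviation of 1.13, against 0.734 to 0.866 on the other 5 region arrays of suboptimal females. The sex difference of contig31511 was -0.879 in the optimal abdomen and -5.06 to -3.1 in the other 7 strata.

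Other splits of the 16 RNA types within strata, 100 in number with the real one included, were counted for each comparison across strata. For sex the real split called 6531 contigs and the highest other split 0, and 1 of 100 was as large. For abdomen it called 13276 (highest other 11563, 1 of 100) and for thorax 2136 (highest other 2716, 2 of 100). For leg it called 2772 (highest other 6301, 2 of 100) and for head 1996 (highest other 12071, 3 of 100). Splits that mix the real groups leave real differences in the spread they are tested against, which can lower their counts. Few splits were as large, but this comparison cannot exclude chance. The head split with 12071 contigs had the abdomen in the place of the head in 4 of 4 strata and the leg split with 6301 had it in 3, so these splits reflect the abdomen. The thorax split with 2716 held the thorax in 1 stratum, the head in 1, the leg in 2 and the abdomen in 0, so a mixture of regions called more contigs than the thorax itself. In it the abdomen lay among the other regions in every stratum, as it does for the thorax itself. The abdomen may therefore enter both counts. The abdomen split with 11563 kept the abdomen in 4 of 4 strata and shuffled the other regions. For nutrition the real split gave 0 contigs, the highest other split 2, and 100 of 100 splits gave as many, which a real count of 0 makes certain, so this says nothing about chance.

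The first pattern was that 4 region arrays of suboptimal animals matched another region pair than their labels. Probes of a contig did not agree less on these arrays: their intraclass correlations were 0.605 to 0.791, within the 0.561 to 0.822 of the optimal region arrays. The lowest of 4 arrays will often lie above the lowest of 16, and this measure also rises with the differences an array carries. Noise between the probes of a contig therefore cannot be excluded. Noise of a single hybridisation that the probes of a contig share was not tested. A region profile that truly differed in suboptimal males would let arrays close around triangles of regions, if each label stood for 1 RNA. The share of variance that did not close had a median of 0.719 there, above the highest optimal triangle of 0.508. Suboptimal females, with 1 of the 4 arrays, had a median of 0.492 and a highest of 1.14. Hybridisation noise or separate pools would also keep triangles from closing, and some optimal male pairs were averaged over both dye orientations. These values therefore cannot exclude a different profile. Other RNA on these arrays than their labels name also stays open: against the optimal profile of the other sex, 3 of 12 suboptimal arrays and 0 of 16 optimal arrays matched another pair by more than 0.1.

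The second pattern was the sex difference, measured with male RNA in Cy3 on every sex array. A dye effect common to all arrays is argued against, since the dye effects of region arrays and of nutrition arrays had a covariance of -0.00214, while the mean of the sex arrays had a standard deviation of 0.452. A dye effect of the sex arrays alone cannot be told apart from sex, because 0 sex arrays carried female RNA in Cy3. Sex itself, and a change in tissue make-up with sex, also stay open.

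The third pattern was that the nutrition difference of the thorax lay along the thorax profile. Shared RNA between the arrays and the profile is argued against, because the lowest of the 4 slopes on the profile of the other sex was 0.357 on the optimal profile and 0.13 on the suboptimal. Dye orientation is argued against by mean slopes that differed by 0.00402 between orientations. A lower share of thorax tissue in the suboptimal pools may have given the same pattern, since the mean slope over contigs on the minus side of the profile was 0.427, and it cannot be told apart from a change within the tissue. A biological effect of nutrition on the thorax stays a hypothesis.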

How the results depend on the processing

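The plain fit, array weights, removal of spatial trends, optimal or suboptimal arrays alone and both rules for doubted arrays were chosen after the results were seen. None of the 12 differences printed for contigs named for a region, sex or nutrition changed sign in the alternatives run for them. The interaction contigs contig17745 and contig03777 stayed past the threshold in 57 of 57 fits, those with 1 array left out included, but the near-zero values of contig17745 in the female head and leg changed sign in some. Some correlations changed sign with 1 array left out: for male and female nutrition in the abdomen, 0.00194 went to -0.0941, and for nutrition and sex 0.0296 went to -0.168 in the head, -0.363 to 0.0305 in the leg and -0.0826 to 0.105 in the abdomen. Slopes of nutrition also changed sign: -0.085 on the male leg profile went to 0.0863 and -0.0203 on the male abdomen profile to 0.00608 with 1 array left out, and -0.0371 on the female leg profile to 0.0149 with dye-swap pairs averaged, where the male abdomen slope was -0.088. Centring on medians, the median of the probes, the series value table and removal of spatial trends left the counts across strata, those averaged over sexes or nutrition within a region, and both F tests within 1.5 times. Smaller counts moved more: centring and removal of spatial trends each took nutrition in the abdomen from 0 to 3 in males and from 0 to 2 in females, and centring took nutrition by sex in the abdomen from 7 to 3. The cause was not tested for the changes below. Arrays alone by nutrition, single arrays left out, direct arrays alone, averaged dye-swap pairs and both fits without doubted arrays rest on fewer arrays or values. Fewer calls in them need not mean smaller differences. Higher region counts without doubted arrays can follow from the rule that picked those arrays.

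Leaving out each array in turn gave, as lowest to highest, 3234 to 8891 contigs for sex across strata, 0 to 1 for nutrition across strata, 1316 to 2759 for head, 1366 to 3374 for thorax, 1072 to 4715 for leg and 11553 to 13751 for abdomen. Within regions it gave 43 to 401 for nutrition in head, 217 to 2707 in thorax and 0 to 4 in abdomen, and for sex 1499 to 6079 in head, 3146 to 8921 in thorax, 2971 to 12612 in leg and 7 to 1481 in abdomen. Nutrition by sex went from 341 to 1194 and nutrition by region from 13 to 116.

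With all 48 arrays as the unit, nutrition across strata gave 35 contigs, head 5615, thorax 5597 and leg 6470. With the 16 fitted values as the unit, nutrition gave 0 in head and 1 in thorax, and sex gave 0 in head, 2266 in thorax, 5176 in leg and 0 in abdomen. Direct arrays alone gave 2347 for sex across strata, 0 for sex in head, thorax, leg and abdomen, and for nutrition 0 in head and 396 in thorax. Their sex fits had no dye term. Averaging dye-swap pairs gave 965 for head, 2 and 6 for nutrition in head and thorax, 1359 for sex in abdomen, 63 for nutrition by sex and 1 for nutrition by region. Without a dye effect sex in the abdomen gave 290.

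Without the 7 doubted arrays the counts were 1740 for sex across strata, 4100 for thorax, 6500 for leg, 1 for nutrition in abdomen, 3442 for sex in thorax, 53 for sex in leg and 72 for nutrition by region. Without the 11 arrays doubted with no margin they were 1594, 4741, 6155, 14, 4558, 50 and 251 in that order, with 2463 for nutrition in thorax, 539 for sex in head, 2411 for sex in abdomen and 1048 for nutrition by sex. The plain fit gave 19503 for sex, 250 for nutrition, 6038 for head, 5062 for thorax and 6711 for leg. Array weights gave 3331 for thorax, 5747 for leg, 489, 6756 and 1 for nutrition in head, thorax and abdomen, 1696 and 1226 for sex in head and abdomen, 1784 for nutrition by sex and 85 for nutrition by region. Optimal arrays alone gave 0 for sex, 246 for head, 392 for thorax, 1233 for leg and 8448 for abdomen. Suboptimal arrays alone gave 1 for head, 16 for thorax, 0 for leg and 1953 for abdomen.

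Intensities as deposited without background correction, quantile normalization between arrays, a filter on dim probes, slide as a block and both alternatives of the gene set tests were planned and not run, since the values are ratios without intensities, slides or gene names. Signal over background is not known for these arrays, so its limit on precision was not measured.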

Other observations

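The array labelled LFL-SFL, the optimal against suboptimal female leg, had 14.9% of its probe variance between blocks of array positions, where the next highest array had 2.18% and the median was 0.472%. It also had the lowest agreement between probes of a contig, an intraclass correlation of 0.416. Removing spatial trends left 0 contigs for nutrition in the leg.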
